A study of Oryza sativa Japonica Group with 5 samples.

How the data were processed

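Genomic DNA of 2-week-old rice seedlings was the material of all 5 libraries. The DNA was sheared to fragments of 100 to 500 bp, and 5 µg per precipitation was denatured and left to refold in a buffer of pH 5.5, per the labels' protocols. I-motifs are folded structures that C-rich single strands can form, and acidic buffer favours them. The antibody iMab, which recognises this fold, was used at 3 µg in 3 precipitations called biological replicates by the series' design text. The other libraries were 1 input library and 1 precipitation with IgG. BWA, SAMtools, Picard and MACS2 2.1.1 are named in the submitters' processing notes, without a role or order for each.

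The file analysed here is a list of the whole series with 1475053 putative i-motif-forming sites. No column of it holds values per library, so the 3 iMab, 1 input and 1 IgG libraries were not compared and their depth is not analysed here. Each site has a chromosome, start, end, strand, sequence on the C-rich strand, length, number of C runs, mean C-run length and a score. The list is named as one of regular sites. A further column, read here as the number of interruptions, is 0 at every site. Densities and shares therefore describe the listed regular sites and may not cover all putative i-motif sites. The score per site was deposited by the authors. How it was computed, the search tool behind the list and the genome build are not given in the sources used here. From the values, positions count from 1 with both ends included, every site holds 4 C runs, and no score lies above -40. More negative scores went with longer C runs, so the score was used only to rank or filter sites within the list. Nothing in the list says which sites were bound by the antibody.

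Sites that overlapped on the same strand were merged into 645216 loci, because overlapping intervals are not independent. Densities were taken over the span from position 1 to the last site of each chromosome. Runs and loops were read from the sequence of each site with 4 separate runs of 2 to 5 C, the parsed sites. The remaining 4.79% of sites did not match this form. They include sites with a run of more than 5 C, which can be divided in several ways. A copy is an exact recurrence of a site sequence in the list. The chance level of copies came from 20 permutations that exchanged loop sequences of equal length between parsed sites and kept the C runs. Windows were 1 Mb for densities and 100 kb for correlations, and windows cut short by the end of a span were left out.

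The list has no replicate libraries, so the 12 chromosomes served as the unit of spread. Each SD and n in the text is over chromosomes unless another unit is named, and each such p measures spread between chromosomes, not between plants. Effects per chromosome were tested with a two-sided exact sign-flip permutation test over all 4096 sign patterns, whose smallest p is 0.000488. Differences between chromosomes were tested by permuting windows 100000 times, with a smallest p of 1e-05. Neighbouring windows are not independent, so that p is too small. P values were adjusted by the Benjamini-Hochberg method over 22 tests. Binomial confidence intervals are exact Clopper-Pearson intervals at 95%, and they cover counting error only.

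Site classes were set after the sequences had been seen. Triplet sites have the form of 3 units of CC plus A, G or T followed by CC, 11 bases in all. Telomeric sites repeat the plant telomere unit of 7 bases, and poly-C sites hold C alone. Long repeated sites have at least 18 bases and at least 50 identical copies and are neither telomeric nor poly-C. A merged locus belongs to such a class if any of its sites does, and it is single-copy if all of its sites are. Long repeated sequences were linked into groups where at least 50% of the copies of the rarer sequence lay at a fixed distance, within 2000 bases, from the other on the same strand. A sequence without such a link formed a group of its own.

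The rule fixed before the data were examined named genes by their number of sites. It could not be applied, because no genome or annotation of the list's build was at hand. The gene table supplied is of assembly ASM3414082v1, whose genes run past the last site on 12 of the 12 chromosomes. Planned comparisons with genes, gene lists, gene starts, GC content, repeats and shuffled sequence were therefore not run, and no gene is named. Sequences and regions are named by rank instead: the most copies, the most loci, the longest locus or the lowest score. They were chosen after their values were seen. Neither was read-derived enrichment tested.

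Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used. The functions were tested on simulated data before use. A planted strand bias of 0.58 on the log2 scale was recovered as 0.59 in 24012 simulated sites, and 58 of 60 planted pairs of copies 9 kb apart were found as neighbours. Merged loci matched a base-by-base count in 24 of 24 chromosome strands. Alternatives planned or added were the unmerged list, scores of -45 or lower, scores under -40, 1 site per locus, other window sizes and class limits, and leaving out each chromosome.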

Results

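The series addressed where i-motifs form in the genome of rice (Oryza sativa, Japonica group, cultivar Nipponbare) and how they relate to transposable elements. An i-motif is a four-stranded fold in which cytosines of a C-rich strand pair with each other. Immunoprecipitation with the iMab antibody was done on refolded genomic DNA of 2-week-old seedlings in 3 replicates, beside 1 input library and 1 IgG library. The values below come from the list of 1475053 putative i-motif-forming sites, named regular, which carries no read counts. They describe the sequences that could fold, not their binding by the antibody. Positions are those of the list, whose genome build is not given in the sources used here, so no gene annotation is attached to them.

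Putative i-motif sites were dense on every chromosome. The merged loci numbered 645216 and covered 4.41% of the chromosome spans. Their density averaged 1728 loci per Mb ± 59.4 (SD, n = 12 chromosomes). Chromosome 5 had the highest density, 1851 loci per Mb, and chromosome 11 the lowest, 1627 loci per Mb. Of the variance in loci between 1-Mb windows, 10.7% lay between chromosomes (permutation test, p = 1e-05, the smallest possible here; adjusted p = 0.00022). The median locus was 22 bases long, and 49.9% of loci held a single deposited site.

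**Figure D1:**
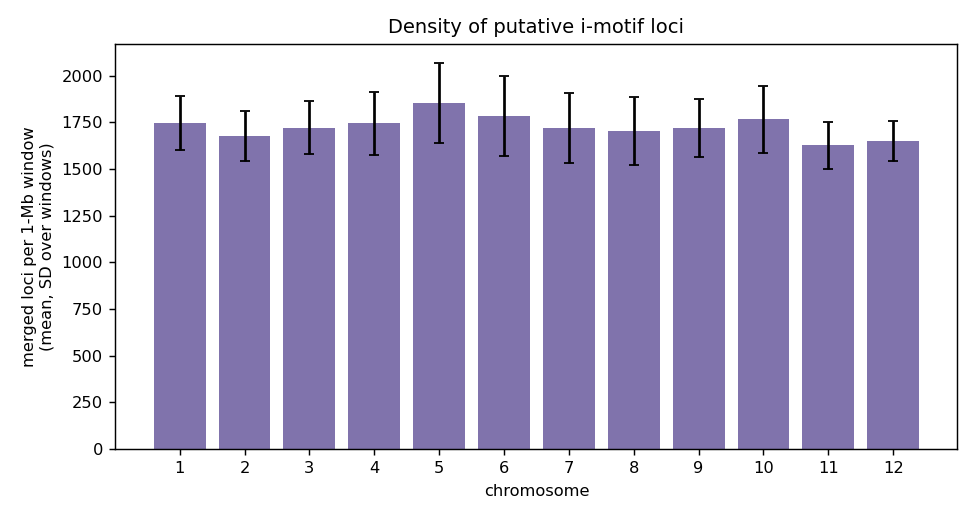
Merged putative i-motif loci per 1-Mb window on each chromosome. Bars give the mean over windows and error bars the SD over windows. Chromosome 5 has the highest mean, 1852 loci, and chromosome 11 the lowest, 1627 loci.

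The C-rich strand was the plus strand as often as the minus strand. The log2 ratio of plus to minus loci averaged -0.00023 ± 0.026 (SD, n = 12; exact sign-flip permutation test, p = 0.978, adjusted p = 0.978). Single chromosomes ranged from -0.041 on chromosome 7 to 0.045 on chromosome 8. Locally, strands were not evenly mixed. Among neighbouring loci at most 100 bases apart, 74.3% ± 1.41 (SD, n = 12) lay on the same strand, above 50% on 12 of 12 chromosomes (exact sign-flip permutation test of the log2 share over 50%, p = 0.000488, adjusted p = 0.000767). Between 1000 and 10000 bases the share was 49.3% ± 0.473, below 50% on all but 1 chromosome (exact sign-flip permutation test, p = 0.000977, adjusted p = 0.00126). Plus and minus loci rarely overlapped. The overlapping share of plus loci was 0.373% ± 0.0350, against 4.12% ± 0.137 after the minus loci were shifted around their chromosome (exact sign-flip permutation test, p = 0.000488, adjusted p = 0.000767). Part of that gap is fixed by the motif, since a base in a C run cannot lie in a C run of the other strand.

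Most sites were built from short C runs and short loops. The median site had 17 bases, with quartiles of 14 and 21 and a range of 11 to 49. In the parsed sites, which hold no run of more than 5 C, runs of 2 C made up 61.5% of runs. Runs of 3 C made up 21.7%, runs of 4 C 12% and runs of 5 C 4.83%. Every run had at least 3 C in 2.44% ± 0.0887 of the parsed sites (SD, n = 12), or 34246 sites. This share depended on the sites kept, with 4.30% for scores of -45 or lower, 2.92% with 1 site per locus and 2.87% for scores under -40. Every run had at least 4 C in 1711 parsed sites and 5 C in 80 parsed sites. At the other end, 184850 sites, 13.2% of the parsed sites, had 4 runs of 2 C each.

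In the parsed sites, loops of 1 base made up 50.0% of loops, loops of 2 bases 13.2% and loops of 3 bases 13.8%. Loops of 8 or more bases made up 3.39%, and the longest had 15 bases. In loops of 1 base the nucleotide was G in 39.8% ± 0.403, T in 36.9% ± 0.354 and A in 23.3% ± 0.280 (SD, n = 12). Read from the 5′ end of the C-rich strand, the first loop averaged 2.49 bases, the second 2.46 and the third 2.44. The first was longer than the third by 0.051 bases ± 0.010 (SD, n = 12; exact sign-flip permutation test, p = 0.000488, adjusted p = 0.000767). The difference was 0.105 bases with 1 site per locus (exact sign-flip permutation test, p = 0.000488) and 0.024 bases for scores of -45 or lower (exact sign-flip permutation test, p = 0.000977). The search rule behind the list is unknown, so these p values cannot tell an effect of that rule from one of the sequences. A CG dinucleotide, the main context of cytosine methylation in plants, was present in 70.7% ± 0.370 of sites. It was present in 80.6% ± 0.442 of long repeated sites, 75.4% ± 0.971 of triplet sites and 69.1% ± 0.847 of single-copy sites. These classes differ in length, which was not matched, and the differences were not tested.

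The deposited score followed the length of the C runs. Within chromosomes, the score with its sign changed had a mean Spearman rho of 0.577 ± 0.00707 with mean run length (SD, n = 12). Its rho was -0.162 ± 0.00970 with mean loop length and 0.0909 ± 0.0110 with site length (exact sign-flip permutation tests over 12 chromosomes, each p = 0.000488 and adjusted p = 0.000767). These correlations are across sites, and sites are not independent replicates. If 1 rule gave every score, the direction would be the same on each chromosome, so these p values say little beyond that rule. The median score was -45, and 17.7% of sites stood at the limit of -40. The lowest score, -90, was given to 37 sites. The commonest of them was CCCCCTCCCCCTCCCCCTCCCCC, with 16 sites. Sites with a mean run of 2 C had a median score of -41, and the 119 sites with a mean run of 5 C one of -88.

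Triplet sites were the most abundant class of repeated sites. The 27 triplet sequences made up 150206 sites, 10.2% of the list, in 84731 loci. They are nearly all of the 150207 sites of 11 bases, the shortest length. At 11 bases, 99.9991% of parsed sites recurred even after loops were exchanged between sites, so the mere recurrence of triplet sites follows from their length. That exchange does not bear on how common each triplet sequence is. Sequences with CCG, CCT or CCA throughout are true triplet repeats, and the others mix these units. CCGCCGCCGCC alone had 50032 sites, 133.8 per Mb ± 11.1 (SD, n = 12), and stood exactly at the score limit of -40. CCTCCTCCTCC followed with 15501 sites, 41.1 per Mb ± 4.79, and CCACCACCACC with 8124 sites, 21.7 per Mb ± 2.98. Both of these had a score of -43, so every triplet site lay within 3 score units of the limit.

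Identical copies were common well beyond the triplets. The list held 646664 distinct sequences, and 63.6% ± 2.54 of sites (SD, n = 12) had a sequence found 2 or more times. For sequences found 10 or more times the share was 43.2%. Of the parsed sites 64.7% were repeated, against 42.5% ± 0.0273 (SD over 20 permutations) after loops were exchanged between sites. Short sequences recur by chance, so the shares were compared by length. Among sites of 12 to 15 bases 96.2% of the parsed sites were repeated, against 95.3% after the exchange. Among sites of 16 to 19 bases the shares were 55.9% and 24.3%. Among sites of 20 or more bases, 37.6% of the parsed sites were repeated, against 0.567% ± 0.0128 (SD over 20 permutations) after the exchange. A sequence found 10 or more times accounted for 20.1% of these longer sites, and for at most 0.00742% in any of the 20 permutations.

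**Figure D2:**
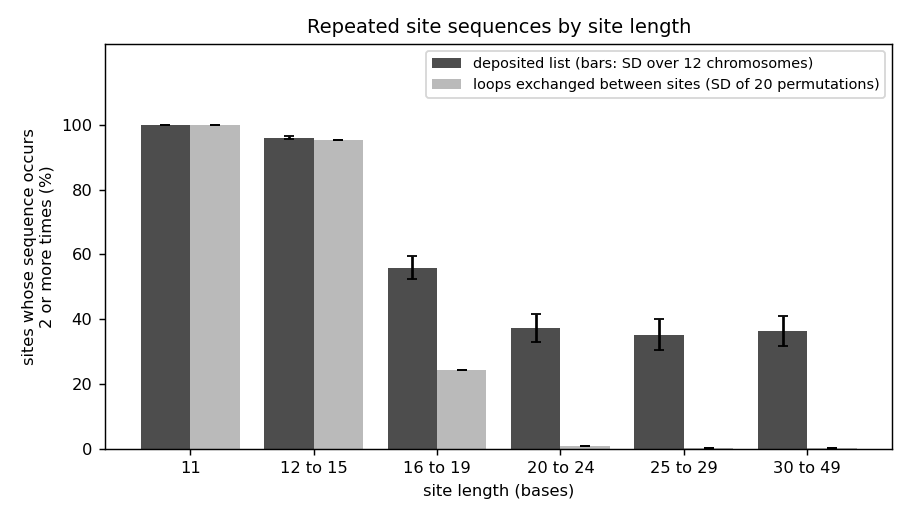
Share of sites whose exact sequence occurs 2 or more times in the list, by site length in bases. Dark bars are all sites of the deposited list with the SD over 12 chromosomes, and light bars are the parsed sites alone with loops exchanged between them and the SD over 20 permutations. In sites of 20 to 24 bases the share is 37.2% of all sites, 38.0% of the parsed sites and 0.750% after the exchange.

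Long repeated sites, of at least 18 bases and 50 copies, came to 72435 sites in 52690 loci. They had 588 sequences. Linking by fixed distances gave 250 groups, of which 162 held 1 sequence alone. Of all 250 groups, 210 had a leading sequence on all 12 chromosomes, and the 10 with the most sites held 46.8% of long repeated sites. CCCAAGCCAACCCAGGCC had the most copies, 1570, at 4.34 per Mb ± 1.62 (SD, n = 12). It reached 7.08 per Mb on chromosome 5 and 2.14 per Mb on chromosome 3. CCATGCACCCACAGCCCACC had 1092 copies, from 1.65 per Mb on chromosome 3 to 4.05 per Mb on chromosome 10. CCCGGCCGTCAGCCGCCC had 1072 copies and led a linked group of 48 sequences and 8295 sites. The sequence of 31 bases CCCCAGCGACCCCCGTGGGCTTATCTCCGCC had 786 copies. The copies lay on both strands, for example 824 plus and 746 minus for CCCAAGCCAACCCAGGCC.

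Neighbouring copies of a long repeated sequence recurred at set distances. Between 8.75 and 9 kb there were 2029 pairs of neighbouring identical copies, 1996 of them on the same strand. From 8.5 to 9.5 kb the same-strand share was 95.4% of 3008 pairs (95% confidence interval 94.6% to 96.1%). Beyond 50 kb it was 49.1% of 48805 pairs (48.6% to 49.5%). Pairs of linked sequences in the same repeat are not independent, so these intervals are too narrow. The group led by CCCGGCCGTCAGCCGCCC gave 31.8% of the pairs at 8.5 to 9.5 kb.

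**Figure D3:**
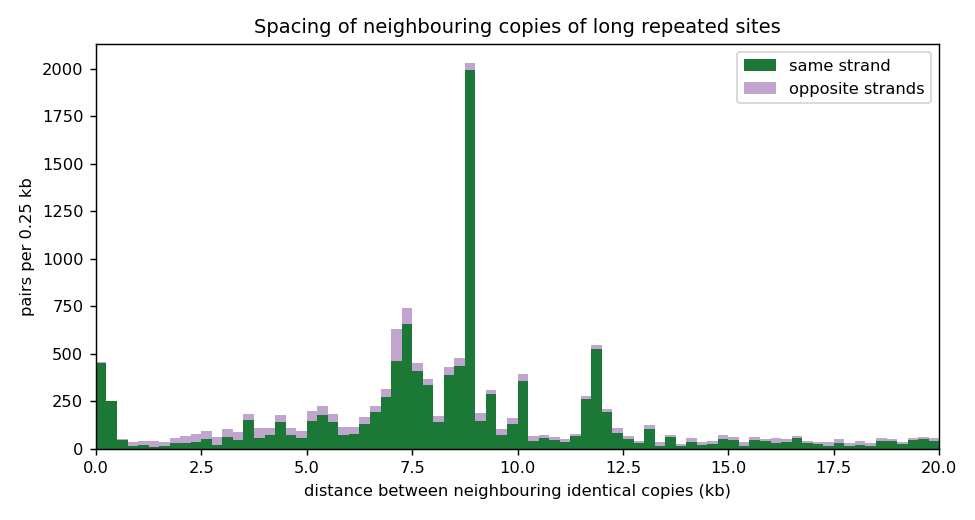
Number of neighbouring identical copies of long repeated sites per 0.25 kb of distance in kb, stacked by strand. The tallest bar, from 8.75 to 9 kb, holds 2029 pairs, 1996 of them on the same strand.

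Long repeated loci were unevenly spread. Chromosomes 5 and 4 had 183.6 and 182.1 such loci per Mb, and chromosomes 3 and 2 had 97.5 and 100.6. Between chromosomes lay 8.21% of the variance of 1-Mb windows (permutation test, p = 0.00128, adjusted p = 0.00156). Triplet loci varied less, with 6.11% of the variance between chromosomes (permutation test, p = 0.0189, adjusted p = 0.0199). The difference between these shares was not tested. The window with the most loci of all was chromosome 6, 18000001 to 19000000, with 2697 loci, of which 710 were long repeated. Next came chromosome 5, 11000001 to 12000000, with 2449 loci, of which 616 were long repeated.

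Long repeated and triplet loci went opposite ways between inner and outer parts on all 12 chromosomes, in the same direction on 11 of them. Long repeated loci averaged 163.1 per Mb ± 31.8 (SD, n = 12) in the inner 60% of the span and 112.8 per Mb ± 30.6 in the outer 20% at each end. Their inner to outer log2 ratio was 0.55 ± 0.33 (exact sign-flip permutation test over 12 chromosomes, p = 0.000977, adjusted p = 0.00126). Triplet loci went the other way, with 214.4 per Mb ± 11 inside and 245.8 per Mb ± 17.4 outside, a log2 ratio of -0.20 ± 0.11 (exact sign-flip permutation test, p = 0.000977, adjusted p = 0.00126). Long repeated loci were denser inside and triplet loci denser outside on 11 of 12 chromosomes each. Chromosome 4 was the exception for both, with log2 ratios of -0.088 for long repeated and 0.026 for triplet loci. All loci together were slightly denser inside, with a log2 ratio of 0.043 ± 0.046 (exact sign-flip permutation test over 12 chromosomes, p = 0.0117, adjusted p = 0.0129). For single-copy loci the ratio was -0.079 ± 0.075 (exact sign-flip permutation test, p = 0.00732, adjusted p = 0.00848), and it was lost with the outer 10% at each end (-0.0013, exact sign-flip permutation test, p = 0.951).

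Across 100-kb windows within a chromosome, triplet and long repeated loci were negatively related. The mean Spearman rho was -0.12 ± 0.051 (SD, n = 12) and the mean Pearson r -0.067 ± 0.033, negative on 12 of 12 chromosomes for both (exact sign-flip permutation tests, each p = 0.000488, adjusted p = 0.000767). The size of the relation depended on the setting. The mean rho was -0.29 ± 0.13 in 500-kb windows and -0.18 ± 0.053 for the unmerged list (exact sign-flip permutation tests, each p = 0.000488). Triplet loci rose with single-copy loci (mean rho 0.308 ± 0.100, mean r 0.312 ± 0.0895), and long repeated loci fell with them (mean rho -0.390 ± 0.0767, mean r -0.436 ± 0.0774). Each of these had p = 0.000488 in the exact sign-flip permutation test over 12 chromosomes (adjusted p = 0.000767).

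**Figure D4:**
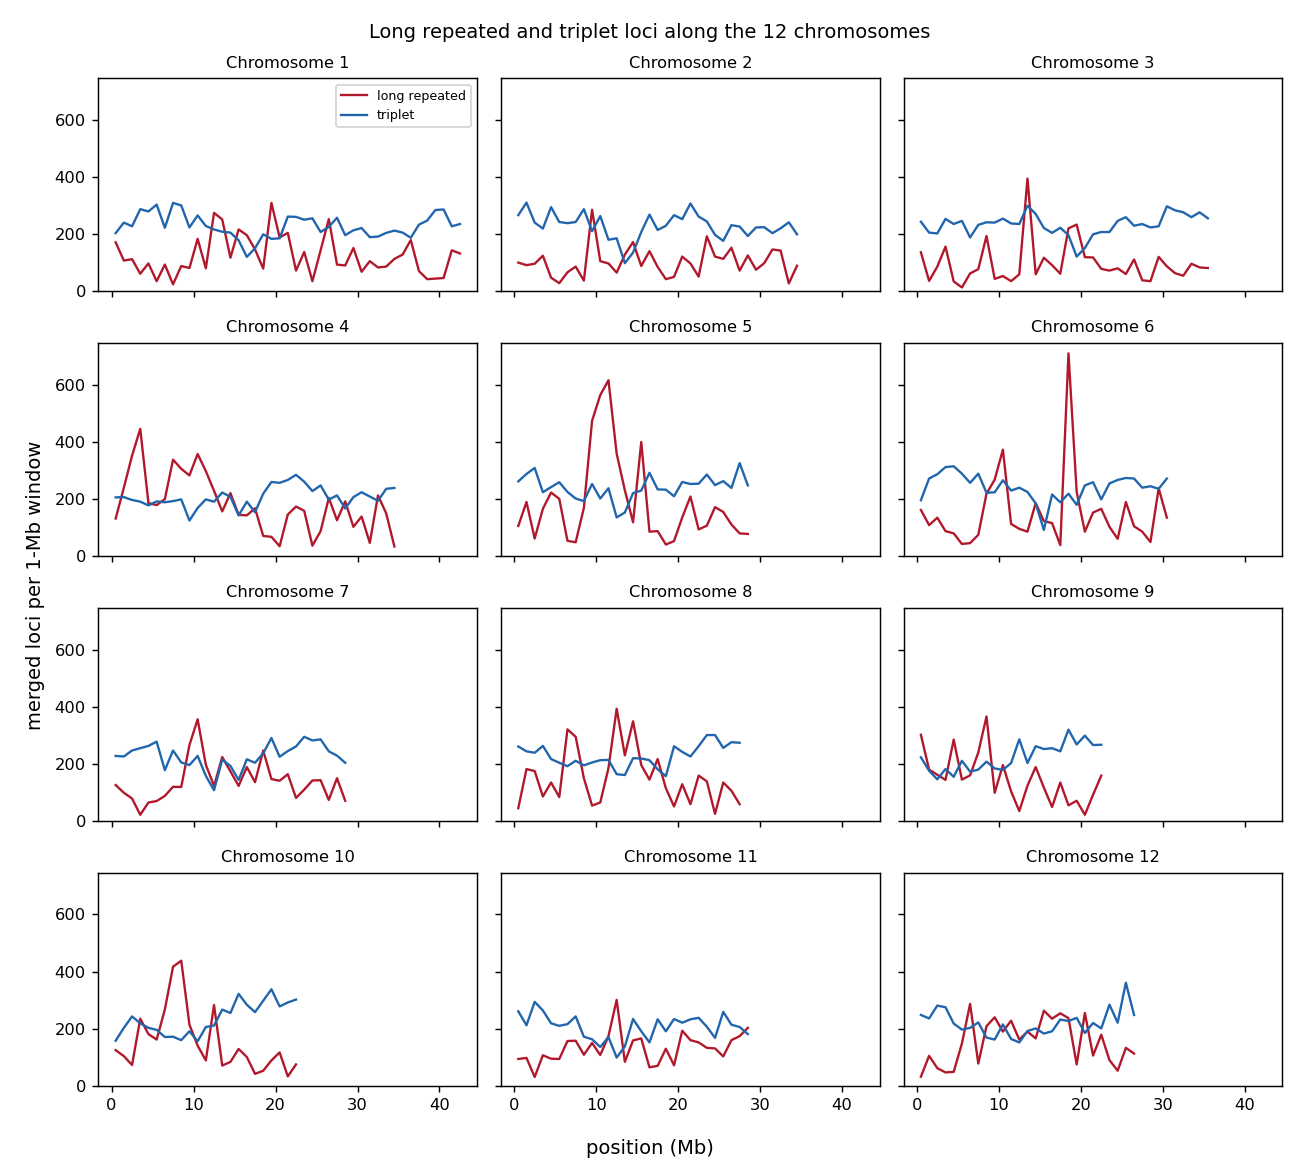
Merged long repeated loci (red) and triplet loci (blue) per 1-Mb window against position in Mb, 1 panel per chromosome. Long repeated loci form peaks, often several per chromosome, which reach 710 loci on chromosome 6 and 616 on chromosome 5. They average 163.1 per Mb in the inner 60% of the span. Triplet loci average 214.4 per Mb there and 245.8 per Mb in the outer parts.

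Telomere repeats lay at the chromosome ends, on the plus strand at the start and on the minus strand at the end. The plant telomere strand with C runs repeats CCCTAAA, and its 24-base site CCCTAAACCCTAAACCCTAAACCC occurred 472 times on 10 chromosomes. Within 10 kb of the start of the span there were 272 such sites on 8 chromosomes, all on the plus strand. Within 10 kb of the last site there were 189 on 5 chromosomes, all on the minus strand. The remaining 11 were interior. The longest locus of the whole list was one of these arrays, chromosome 4, positions 1001 to 1894, with 894 bases and 126 overlapping sites. Chromosome 7, positions 29696795 to 29697621, followed with 827 bases and 115 sites. Outside the telomere repeats, the longest loci were on chromosome 2, at 23499684 to 23500006 on the minus strand (323 bases) and 29403662 to 29403965 on the plus strand (304 bases).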

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

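Set before the data were examined were the unmerged list for loci per Mb and strand balance, scores of -45 or lower and left-out chromosomes for strand balance, and sites of at most 100 bases for the score; the others were chosen after seeing the data. Of 208 alternative values over 14 results, 163 of 168 that left out a chromosome and 29 of 40 others kept direction and side of the threshold or, for values without a test, moved by less than 1 SD. The remaining 5 with a chromosome left out changed the sign of the strand ratio. Loci per Mb were 3951 for the unmerged list, 980.9 for scores of -45 or lower and 1471 for scores under -40, each because it keeps other intervals. The strand log2 ratio, never past the threshold, changed sign to 0.0086 in the unmerged list and to 0.00070 for scores of -45 or lower; without 1 chromosome it ran from -0.0044 to 0.0035. The share of sites with every run of 3 or more C was 2.92% with 1 site per locus, 4.30% for scores of -45 or lower and 2.87% for scores under -40. The share of repeated sites was 36.7% at 20 or more bases. Same-strand neighbours reversed to a log2 share of -0.021 at 1000 to 10000 bases. The single-copy ratio of inner to outer density was -0.0013 with the outer 10%; the cause was not tested. Scores of -45 or lower include 0 triplet sites, and 0 sites exceed 100 bases, so that limit tests nothing. Not run, for want of a genome or of values per library, were the alternatives of 50 flanking bases for copy number and all those for genes, gene lists, gene starts, repeats, GC windows, shuffled sequence and the iMab, input and IgG libraries. No paired analysis was possible because no column carries values per library. Sequencing depth sets no limit here, since the list holds no read counts.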

Other observations

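An array of a long repeated site stood out on chromosome 11. The sequence CCGATTCTCCCCAGCTTCGCCGCCC of 25 bases had 198 copies, all on the minus strand between positions 12039799 and 12178950, a stretch of 139.2 kb. The commonest distance between neighbouring copies was 324 bases, found 109 times. It was the only group of long repeated sites on 1 chromosome alone. Interior telomere repeats were few, 11 sites in 6 loci; chromosome 12 had a pair of loci of 43 bases each, at 18242978 to 18243020 and 18252047 to 18252089.

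The tests below were stated before their results were seen, with some exceptions. Added afterwards were the counts per group of linked sequences, those on leading sequences, the 7-kb pairs and the bootstrap intervals. So were the CAG, CTG and CGG context and the 500-kb partial correlation. The patterns were noticed in the same data on which they were tested. The design names no group of samples that bears on them, so no biological explanation was tested between groups.

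Copies of long repeated sites recurred at 8.5 to 9.5 kb from each other. Of 3008 neighbouring identical copies at that distance, 95.4% lay on the same strand (exact binomial 95% interval 94.6% to 96.1%). The share was 94.9% of 1108 pairs when each group of linked sequences was counted by its leading sequence alone, and over 90% in 30 of 33 groups with at least 10 pairs. Independent insertions into the same regions are argued against, since the share exceeded that at 15 to 50 kb by 34.4 percentage points on average (higher on 12 of 12 chromosomes, exact sign-flip permutation test, p = 0.000488). Long tandem runs are argued against too: of 2875 copies with a same-strand copy at that distance before them, 2.50% also had one after. A pair of directly repeated ends of one element, as in retrotransposons with long terminal repeats, remains a candidate explanation, untested against an annotation.

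Most opposite-strand pairs at about 7 kb came from 1 group of linked sequences. Between 7 and 7.25 kb, 165 of 629 neighbouring pairs lay on opposite strands, and 133 of these came from the group led by CCATGCCCCCTCGCCGCCC. Its leading sequence had 81 neighbouring pairs at 4 to 15 kb, with 0% on the same strand. For CCCAAGCCAACCCAGGCC, whose commonest distance was also 7 to 7.5 kb, the same-strand share at 4 to 15 kb was 77.7%. Between 8.75 and 9 kb, 33 of 2029 pairs of all groups lay on opposite strands. At 11 to 12 kb, 93.3% of 952 pairs were on the same strand.

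Near copies of long repeated sites differed in their changes from CG to CA. Of 989 loop G that follow a C, 71.1% had a rarer near copy with A in that place, against 46.5% of 986 other loop G. The ratio was 1.53 (95% bootstrap interval over groups 1.37 to 1.70), and the rate was higher in CG in 102 of 172 groups and lower in 24 (sign-flip permutation test over groups, two-sided, p = 1e-05, the smallest possible). For changes to T the shares were 17.5% and 14.6%, a ratio of 1.2 (0.963 to 1.46; sign-flip permutation test over groups, p = 0.645). Groups were linked by fixed distances and not by likeness of sequence, so near copies of the same repeat can fall in different groups. The groups are therefore not all independent. The bootstrap intervals here may be too narrow, and the p values over groups too small. Deamination of methylated cytosine may contribute. The limits set for it were a ratio over 1.5 for A and under 1.2 for T. The point values, 1.53 and 1.198, met both limits narrowly, but each interval spans its limit. The alternative, that the score limit and the C-run rule let more changes through at CG, also stays open: the ratio for A was 1.28 times that for T (1.03 to 1.59), around the limit of 1.3 set against it. Where G ended a CAG, CTG or CGG, counted together, the share with A was 56.8% of 438, against 38.1% of 548 elsewhere. The shares with T were 16.4% and 13.1%, and neither difference was tested.

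Triplet and long repeated loci were negatively related across 100-kb windows. In 500-kb windows the mean rho was -0.29 ± 0.13, so the relation was not weaker at that larger scale. A single 1-Mb window could still hold many of both. Chromosome 3, 13000001 to 14000000, had 300 triplet and 395 long repeated loci. Given the density of single-copy loci, the mean partial rank correlation was 0.0032 ± 0.063 (SD, n = 12 chromosomes; exact sign-flip permutation test, p = 0.854), so the opposite relations of the 2 classes to single-copy loci could account for their relation at 100 kb. At 500 kb a partial correlation of -0.11 ± 0.16 was left (exact sign-flip permutation test, p = 0.0205). Lack of room cannot be told apart by the limit set: merged sites filled up to 10.4% of a window, but over 10% in only 3 of 3727 windows, with a median of 4.29%. Single-copy loci exclude the other classes by definition, which limits the reading of the partial correlations. Triplet and long repeated loci do not exclude each other, and 2093 loci were both.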
